A study of Mus musculus with 120 samples.

How the data were processed

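T cell receptor beta chain (TCRb) genes were amplified and sequenced from genomic DNA of mouse lungs, labelled as lung metastasis. The labels describe MMTV-PyMT mice, which develop mammary tumors, and FVBN mice without the transgene. They list 120 samples in 16 groups, and 52 of these, in 14 groups, were analysed; the other 68 were not analysed here. Each of the 52 mice had 1 table, in which each line is a clonotype, defined by its CDR3 sequence with its V and J segment.

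Per the file headers, each table gives a read count per clonotype and the deposited read fraction, which is the share of reads that clonotype took. The deposited tables also hold a first and a second normalized clone count, each a score made by the authors. From the values, this score equals reads multiplied by a factor that is fixed for each V-J pair and rounded to whole numbers. The deposited normalized clone fraction is each clonotype's share of the total of that score, per the file headers. How the factors were derived, the aligner and the clonotype caller are not given in the sources used here. The factors of the second normalized count were the same in all mice. The factors of the first differed between 4 sets of mice, here called normalization sets. Factors of V-J pairs with at least 30 reads were called equal within 0.5% plus rounding; by set, a median of 0% of pairs differed within a set and a median of 71.7% to 88.7% differed from other sets. The sets, of 25, 11, 4 and 12 mice, were found from the values and were treated as technical batches. The second normalized count was used as the main value, a choice made before any test was run. All listed clonotypes were productive, so an alternative with productive clonotypes alone was identical.

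Depth differed widely between mice. Reads ranged from 1383 to 908919 per mouse (median 60990) and clonotypes from 128 to 13826 (median 3687.5). The tables held 226139 clonotypes in all. A count of 3 reads, the upper limit that a count of 0 allows, corresponded to 0.00033% to 0.217% of a mouse's reads. These are PCR reads without molecular identifiers and not independent molecules, so intervals and such limits cover counting error only. For 1 mouse, a share of reads is given with its 95% Wilson interval. Between 4 and 624 clonotypes per mouse were rounded to 0 in the second normalized count and did not contribute to shares.

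The groups were taken from the labels, and 11 comparisons were fixed before the data were examined, with their tests, the named-segment rule and most alternatives. For each mouse, 7 summary values were computed: clonality (1 minus Shannon entropy over the log of the number of clonotypes), Shannon entropy in nats, the percent of the repertoire in the 10 largest clonotypes, the percent in clonotypes above 1%, the percent in clonotypes above 0.1%, the number of clonotypes and the mean CDR3 length in amino acids. Each was compared by a two-sided exact permutation test of the difference in means, with Benjamini-Hochberg adjustment over all 77 tests. V and J segments and V-J pairs with a mean of at least 0.1% were tested with limma on log2(percent + 0.1), over all 52 mice with 1 coefficient per group, adjusted within each comparison. This gave 27 segments and 90 pairs. The 10 clonotypes (V, J and CDR3 amino acid sequence) listed in at least 26 mice were tested with limma on log2(ppm + 10), where ppm is the share of the repertoire times 1e6. Morisita-Horn similarity between mice was compared within and between groups by exact permutation of mouse labels, adjusted over the 11 comparisons. The interaction of PLX and PTX was a limma contrast for segments and pairs, and for summary values a permutation of PLX labels within PTX strata with 100000 resamples.

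Named segments followed a rule. Per comparison, up to 10 segments past an adjusted p of 0.05 with the largest log2 difference were named, or the 3 with the smallest p where none passed. Also named were the 8 V and 3 J segments with the highest mean percent, up to 5 V-J pairs per comparison, the 5 most abundant shared clonotypes, the 5 largest clonotypes of single mice and the fixed lists. List 1 held 9 segments reported as deleted from the FVB/N genome (TRBV12-1, TRBV12-2, TRBV13-1, TRBV13-2, TRBV13-3, TRBV14, TRBV15, TRBV16 and TRBV17), of which 4 were abundant enough to test. List 2 held 5 segments known as targets of mouse mammary tumor virus superantigens (TRBV19, TRBV29, TRBV31, TRBV20 and TRBV26), of which 4 were tested, since TRBV31 was listed in no mouse. List 3 held 3 segments typical of invariant NKT cells (TRBV13-2, TRBV29 and TRBV1). List 4 set the TRBJ1 cluster against the TRBJ2 cluster. The summed share of each list, and that of list 1 in the repertoire without TRBV24, were compared by exact permutation tests chosen after the data had been seen. All 34 segment names in the tables matched symbols of the mouse reference annotation GRCm38.p6, which was used for names alone.

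Alternatives fixed in advance were raw clone counts, thinning to the smallest read total, group medians, animal numbers below 34000, the animal number range as a block, other pseudocounts and filters, each clonotype counted once, an arcsine square root scale, fits to the compared groups alone, the Jaccard index, other definitions of shared clonotypes, the number of clonotypes as a covariate, removal of the 10 largest clonotypes, and leaving out each mouse in turn. Alternatives added after the data were seen were the first normalized count, the normalization set as a block with and without the R mice, comparisons or permutations within sets, mice of set 1 alone, removal of TRBV24 clonotypes, removal of the 5 mice with under 1000 clonotypes, and an edgeR quasi-likelihood test on raw reads per segment. No coordinates were used. Statistics ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.

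The limma step was tested on simulated data with the group sizes of PTX against untreated mice. Of 4 changed segments among 27, it recovered 48.5% at a fold of 2, 89% at 4 and 99% at 8. Of 10 changed pairs among 90, it recovered 17.4%, 92.8% and 99.4% at those folds. Of 2 changed clonotypes among 10, it recovered 3%, 12% and 33%. At those folds the false share of calls was 3.96%, 8.72% and 5.26% for segments and 8.42%, 6.26% and 4.97% for pairs. For clonotypes it was 50%, 20% and 10.8%. Most of these lay above the adjusted p threshold of 0.05. With the same group sizes and no shift, the permutation test gave p under 0.05 in 4.33% of 300 simulations.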

Results

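TCRb repertoires were measured in the lungs of 52 mice, each of which was sequenced once. Labels give the day of collection after the letter d. Lungs of MMTV-PyMT mice at d105 came from 6 untreated mice, 5 given PLX, 7 given PTX and 5 given both. PLX is PLX3397 (pexidartinib), an inhibitor of the macrophage growth factor receptor CSF1R, given in chow at 40 mg/kg per day from day 80. PTX is paclitaxel, a microtubule-stabilizing chemotherapy, given at 10 mg/kg every 5 days from day 85. Groups labelled aPD-L1 held 3 mice with that label alone, 4 with PTX and 3 with PLX and PTX; the labels give no dose for it. Anti-PD-1, an antibody against an inhibitory receptor on T cells, was given from day 87 at 1 mg and then 0.5 mg every 5 days. It was given with PLX and PTX to 2 mice labelled R and 2 labelled NR at d105, letters the labels do not expand, and to 7 mice at day 95, and with PTX to 1 mouse. Day 95 also had 3 PTX and 2 PLX+PTX mice, and 2 FVBN mice labelled WTNT were taken at day 80. Reads per mouse ranged from 18275 to 91525 in untreated mice, 21603 to 82214 in PTX, 1383 to 72666 in PLX and 26718 to 580928 in PLX+PTX mice at d105. They ranged from 24242 to 270462 in the 10 aPD-L1 mice, from 19415 to 908919 in the R and NR mice, from 6178 to 215495 at day 95, and were 3427 and 44224 in the WTNT mice. The PTX+aPD-1 mouse had 70748 reads.

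Over all mice, TRBV24 was the most used V segment, with 51.0% ± 25.6 (SD, n = 52) of the repertoire and a range of 8.64% to 97.4%. TRBV1 followed with 19.4% ± 7.24, then TRBV4 with 5.71%, TRBV5 with 4.77%, TRBV26 and TRBV2 with 3.67% each, TRBV19 with 3.10% and TRBV3 with 2.89%. Among J segments, TRBJ2-5 took 28.8%, TRBJ2-7 25.2% and TRBJ2-1 11.1%. TRBV24 shares went with the normalization set: the median was 71.4% in set 1, 21.8% in set 2, 22.4% in set 3 and 26.5% in set 4. All untreated, aPD-L1 and WTNT mice were in set 1, all PLX mice in set 2 and all day 95 mice in set 4, while PTX and PLX+PTX mice of d105 were spread over 2 and 3 sets. Values within a set, or with the set as a block, therefore stand beside many, though not all, of the pooled ones. No exact test of a summary value or of TRBV24 within a set passed after adjustment (adjusted p of 0.381 or more), and those of list sums within a set were not adjusted. Because TRBV24 took so much of the repertoire, removing it shifted the median log2 difference of the other segments, from 1.54 to 0.85 for PLX against untreated, from 0.50 to 0.24 for PLX+PTX against untreated and from -0.64 to -0.29 for PTX at d105 against day 95.

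**Figure D1:**
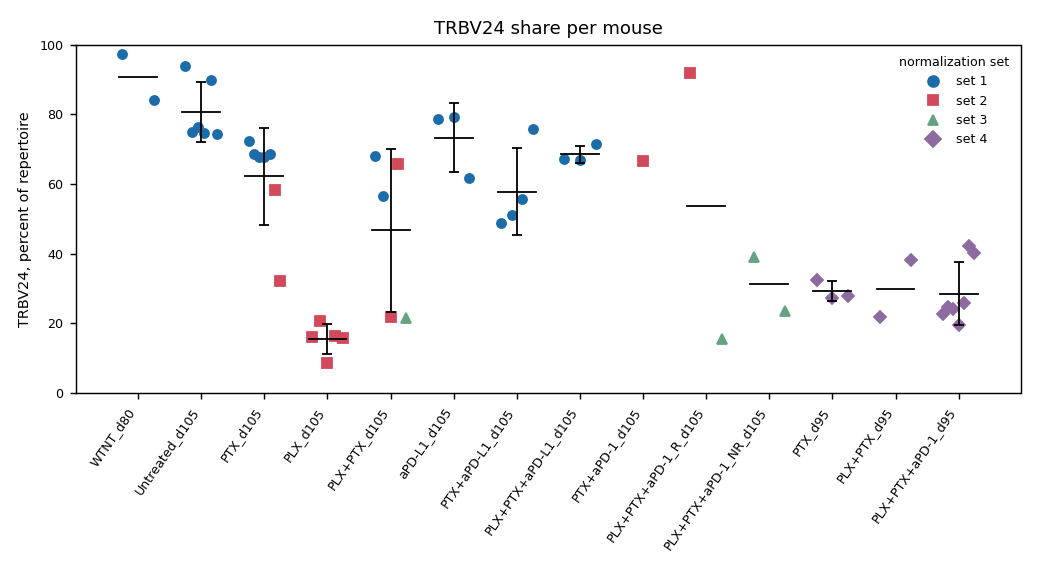
Share of TRBV24 in the repertoire of each mouse (percent, vertical axis) by group, with 1 point per mouse colored by normalization set, a line at the mean of groups of 2 or more and SD bars for groups of 3 or more. The 5 PLX mice lie between 8.64% and 20.6%, below every untreated mouse (74.5% to 93.8%).

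The comparison of PTX with untreated mice at d105 addressed chemotherapy alone. TRBV24 took 62.3% ± 13.9 (n = 7) of the repertoire after PTX and 80.7% ± 8.73 (n = 6) without treatment, and was lower in 7 of 7 PTX mice than in every untreated mouse (exact permutation p = 0.00117, two-sided, not adjusted, a test chosen after the data were seen). Within set 1 it was 69.0% ± 1.95 in 5 PTX mice (exact p = 0.00866, adjusted 0.381). The summed share of the NKT-type segments of list 3 rose from 14.2% ± 6.74 to 23.2% ± 2.61 (exact p = 0.00117, adjusted 0.0397, higher in 7 of 7 mice than the untreated mean); in set 1 it was 22.4% ± 1.78 (exact p = 0.0152). Most of that share was TRBV1, with 21.6% ± 3.19 against 13.7% ± 6.65, whose log2 difference turned from 0.87 to -0.21 in the repertoire without TRBV24. List 1 summed to 1.80% ± 1.42 and 0.656% ± 0.519 (exact p = 0.101, adjusted 0.288), with 2.47% in the PTX mice of set 1 (exact p = 0.0130). In limma, 0 of 27 segments passed, with 6 at an unadjusted p under 0.05, and edgeR called 5. The 3 smallest p belonged to TRBV5 (log2 1.22, SE 0.46, adjusted p = 0.0955), TRBV1 (0.87, SE 0.33) and TRBV4 (1.68, SE 0.65). Within set 1 alone their log2 values were 0.72, 0.83 and 1.03. There 0 segments passed in limma and 4 had an unadjusted p under 0.05. These were TRBV13-3 (1.04), TRBV13-1 (1.24), TRBV12-1 (1.29) and TRBV13-2 (1.51) of list 1. No member of any list passed; adjusted over the list alone, 1 member of list 3 and 0 of the others did. Of 90 V-J pairs 0 passed (10 unadjusted), and of 10 shared clonotypes 0 passed (1 unadjusted). Mean CDR3 length was 13.7 against 13.5 amino acids (exact p = 0.00932, adjusted 0.103; in set 1 p = 0.0606), and none of the 7 summary values passed.

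The comparison of PLX with untreated mice addressed CSF1R inhibition alone, and it held the largest segment differences at d105. TRBV24 fell from 80.7% ± 8.73 (n = 6) to 15.5% ± 4.29 (n = 5), lower in 5 of 5 mice than in every untreated mouse (exact permutation p = 0.00216, the smallest this design allows). TRBV3 rose from 0.0924% ± 0.0565 to 11.1% ± 0.620 and TRBV4 from 0.438% ± 0.268 to 16.6% ± 4.63, each above every untreated mouse in 5 of 5. TRBV2 rose from 0.501% to 8.60%, TRBV5 from 1.48% to 9.24% and TRBV20 from 0.000685% to 1.52%. In limma, 22 of 27 segments passed, 18 higher and 4 lower (edgeR 21). With the set as a block, 18 passed, 16 higher and 2 lower, and these 18 were among the 22 with the same direction; no set held mice of both groups, so the block was linked through PTX, PLX+PTX and R mice. Without the 2 R mice, 16 passed with the block, all among the 22 with the same direction. The largest log2 differences were 5.93 for TRBV3 (SE 0.76; 4.55 with the block) and 5.14 for TRBV4 (SE 0.71; 3.57). Next were TRBV2 (3.87; 2.26), TRBV29 (3.87; 2.67), TRBV19 (3.69; 2.65), TRBV20 (3.41; 3.37), TRBV26 (3.25; 2.40), TRBV5 (2.71; 1.48), TRBV13-3 (2.57; 3.18) and TRBV24 (-2.42; -1.84). Their adjusted p ranged from 2.38e-08 to 0.000114 without the block and from 0.000107 to 0.0340 with it.

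Scaling decided part of the PLX result. In the repertoire without TRBV24, 19 segments passed, 13 higher and 6 lower, and 16 of the other 21 passed in the same direction. TRBV1, the second most used V segment, had 12.9% ± 1.56 against 13.7% ± 6.65 of the whole repertoire; its mean was lower in PLX mice, while the log2 difference, taken on the mean of logs, was 0.14 (SE 0.36). Without TRBV24 it was -2.16, and that of TRBV30 went from 0.17 (SE 0.34) to -2.04. TRBV5 had log2 0.49 without TRBV24 and -0.27 when the set was also a block, and TRBV23 turned from 1.08 to -0.82. All 4 tested members of list 2, the superantigen targets TRBV19, TRBV20, TRBV26 and TRBV29, rose (4 adjusted over the list alone), and their sum rose from 1.32% ± 0.802 to 17.9% ± 3.07 (exact p = 0.00216, adjusted 0.0397, 5 of 5 mice). Of list 1, all 4 tested members rose (4 adjusted over the list alone), but without TRBV24 TRBV13-2, TRBV13-1 and TRBV12-1 had log2 values of 0.07, 0.09 and 0.19 that did not pass. The list 1 sum was 6.10% ± 5.90 against 0.656% ± 0.519 (exact p = 0.00433, adjusted 0.0595), and without TRBV24 7.07% against 4.57% (exact p = 0.470). In the whole repertoire it was 15.8% in PLX mouse 3, which had 1383 reads, and 1.44% to 7.65% in the other PLX mice. Of list 3, 2 of 3 rose (2 adjusted over the list alone). In the TRBJ1 cluster 3 of 5 rose and 1 fell (4 adjusted over the list alone), and its sum rose from 11.1% ± 1.13 to 17.8% ± 3.23 (exact p = 0.00216, adjusted 0.0397). In the TRBJ2 cluster 2 of 6 rose and 2 fell (4 adjusted over the list alone), TRBJ2-5 from 39.1% to 15.9%.

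**Figure D2:**
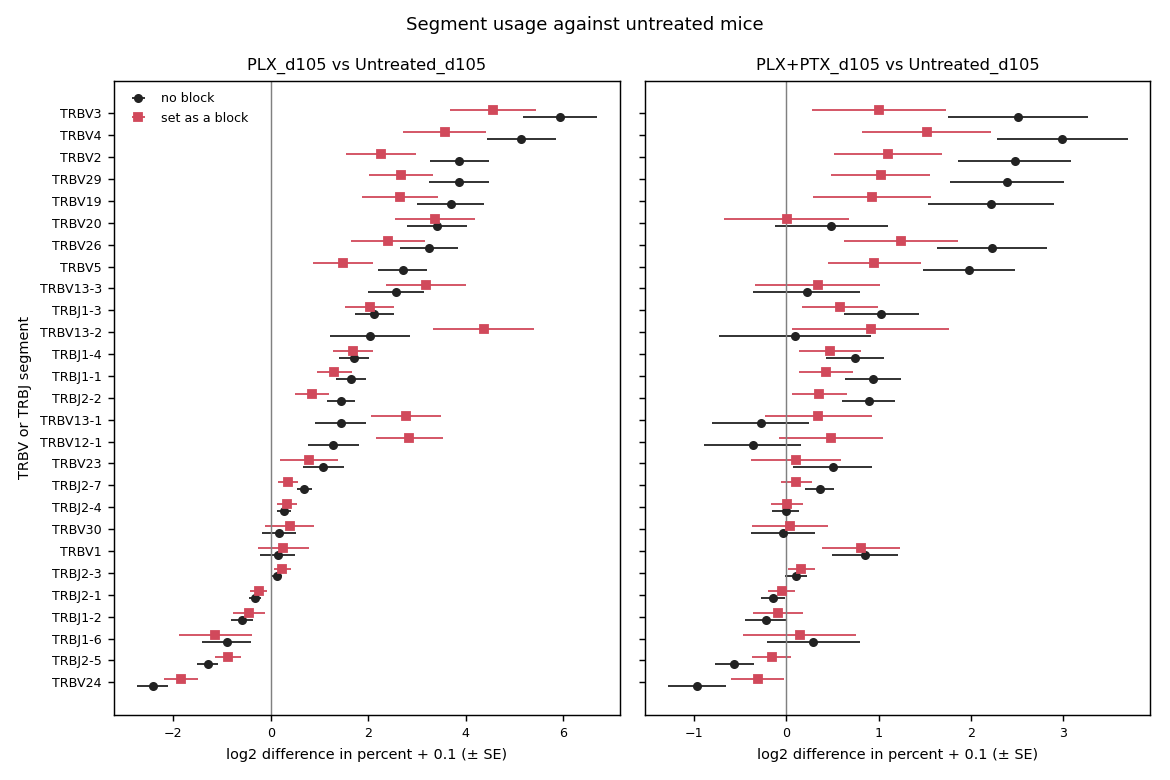
Log2 difference in segment share (horizontal axis, with SE bars) for 27 TRBV and TRBJ segments, PLX against untreated on the left and PLX+PTX against untreated on the right, without a block (circles) and with the normalization set as a block (squares). The value for TRBV3 is 5.93 without and 4.55 with the block on the left, and 2.51 and 1.00 on the right; in the repertoire without TRBV24 5 signs turn on the left, among them TRBV23 from 1.08 to -0.82 and TRBV1 from 0.14 (SE 0.36) to -2.16, and 6 on the right, among them TRBV1 from 0.85 to -0.68.

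Of 90 V-J pairs, 74 passed for PLX against untreated, 62 higher and 12 lower, and 29 with the block. TRBV4 TRBJ2-7 had a log2 difference of 4.94, TRBV3 TRBJ2-7 4.84, TRBV2 TRBJ2-7 3.94, TRBV3 TRBJ2-4 3.81 and TRBV3 TRBJ2-2 3.46. Of 10 shared clonotypes 0 passed in limma (1 unadjusted). The repertoires of PLX and untreated mice separated: Morisita-Horn similarity averaged 0.0611 within groups and 0.00805 between them (exact p = 0.00216, adjusted 0.0238). Every pair within a group also lay within a set, and every pair between groups lay between sets. This test alone therefore cannot tell group from set. Over all pairs of mice the median similarity was 0.0345 within a set and 0.0131 between sets. None of the 7 summary values passed, and the number of clonotypes was 2500 ± 1427 against 3168 ± 1033. Without the 1 PLX mouse under 1000 clonotypes, the within-minus-between difference was 0.0626 (exact p = 0.00476, the smallest possible with 4 and 6 mice, adjusted 0.0524) against 0.0531 with it.

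PLX+PTX was set against untreated mice as the combination of CSF1R inhibition with chemotherapy. The repertoires were larger: Shannon entropy rose from 7.17 ± 0.314 (n = 6) to 8.28 ± 0.474 nats (n = 5), the number of clonotypes from 3168 ± 1033 to 8301 ± 3093 and the mean CDR3 length from 13.5 ± 0.0888 to 13.7 ± 0.0848 amino acids. The share in clonotypes above 0.1% fell from 45.5% ± 12.003 to 9.23% ± 8.34. Each of these 4 values separated 5 of 5 mice from every untreated mouse (exact permutation p = 0.00216, the smallest possible, adjusted 0.0417). Clonality, 0.0729 against 0.0996, did not pass (exact p = 0.0368, adjusted 0.189), nor did the share in the 10 largest clonotypes, 2.89% against 4.98% (exact p = 0.0173, adjusted 0.133). Within set 1, the 2 PLX+PTX mice had entropy 7.92, 17.4% above 0.1% and 6639 clonotypes (each exact p = 0.0357, the smallest possible, adjusted 0.381) and a CDR3 length of 13.7 (exact p = 0.107), too few mice for a value to pass after adjustment. No summary value passed when libraries were thinned to the smallest read total. Thinned differences in entropy, percent above 0.1%, clonotypes and CDR3 length were 0.358, -28.0, 272 and 0.234, against 1.11, -36.3, 5133 and 0.195 without thinning.

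**Figure D3:**
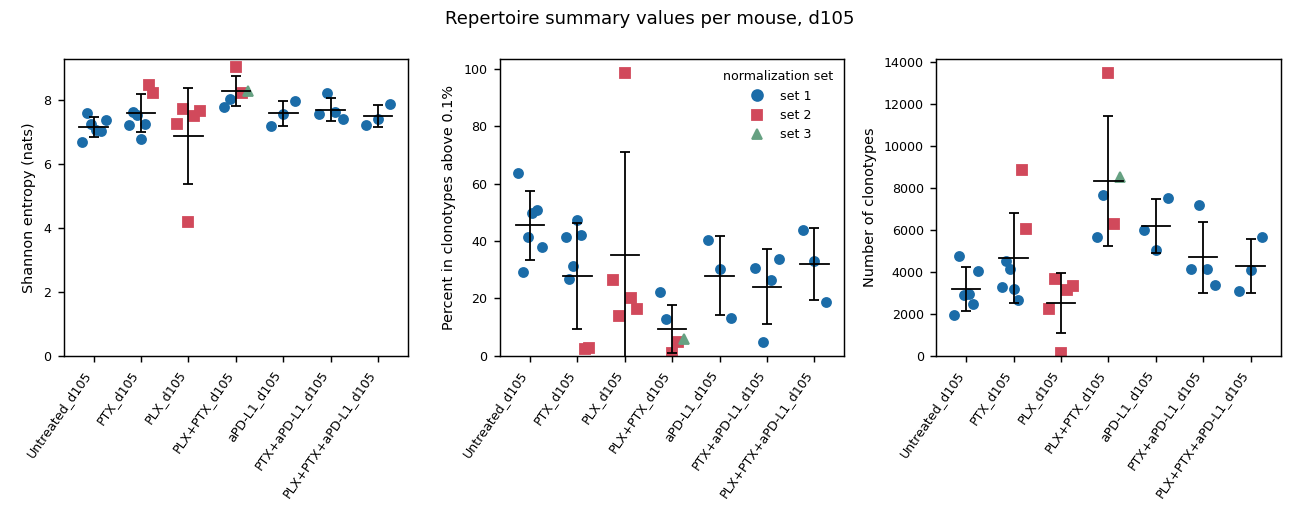
Shannon entropy (nats), percent of the repertoire in clonotypes above 0.1%, and number of clonotypes per mouse at d105 (vertical axes) by group, with 1 point per mouse colored by normalization set, and mean and SD as lines. PLX+PTX mice averaged 8301 clonotypes and untreated mice 3168.

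In segment usage, TRBV24 fell to 46.7% ± 23.3 in PLX+PTX mice (lower in 5 of 5 than every untreated mouse, exact p = 0.00216) and was 62.2% in the 2 mice of set 1 (exact p = 0.0714). TRBV4 rose to 5.92% ± 5.95 from 0.438% ± 0.268 (log2 2.98, SE 0.71), TRBV3 to 2.52% ± 3.08 (2.51), TRBV2 to 4.50% (2.47), TRBV29 to 2.89% (2.39), TRBV26 to 4.17% (2.23), TRBV19 to 3.13% (2.21) and TRBV5 to 6.57% (1.98). TRBJ1-3 and TRBJ1-1 rose by log2 1.03 and 0.94, and TRBV24 differed by -0.96 (adjusted p = 0.0102). In limma 15 of 27 segments passed, 13 higher and 2 lower (edgeR 13), but with the set as a block 0 passed, with adjusted p from 0.301 to 0.777 for those 15 and log2 values of 1.52 for TRBV4 and -0.31 for TRBV24. The share of TRBV1 rose from 13.7% to 21.4% (log2 0.85), which turned to -0.68 without TRBV24. List 2 had 3 of 4 members higher (3 adjusted over the list alone), list 3 had 2 of 3 (2), the TRBJ1 cluster 3 of 5 (3), and list 1 had 0 of 4 (0); in the TRBJ2 cluster 2 of 6 rose and 1 fell (3). The list 2 sum was 10.2% ± 9.46 against 1.32% (exact p = 0.00866, adjusted 0.0680), and 4.66% in set 1 (exact p = 0.0357). Of 90 pairs 47 passed, 41 higher and 6 lower, and 0 with the block. Counting each clonotype once left 0 segments and 0 pairs, and leaving out 1 mouse gave 5 to 15 segments and 0 to 65 pairs. Pairs TRBV4 TRBJ2-7 (log2 2.89), TRBV3 TRBJ2-7 (2.16), TRBV29 TRBJ2-7 (2.12), TRBV26 TRBJ2-7 (2.03) and TRBV5 TRBJ2-7 (1.99) differed most. Of 10 shared clonotypes 0 passed in limma (1 unadjusted), and repertoires were no more alike within than between groups by a margin that passed (difference 0.00291, exact p = 0.251, adjusted 0.629).

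PLX+PTX against PTX asked what CSF1R inhibition added to chemotherapy. The number of clonotypes was 8301 ± 3093 (n = 5) against 4657 ± 2151 (n = 7), which did not pass after adjustment (exact p = 0.0316, adjusted 0.189). TRBV24 was 46.7% against 62.3% (exact p = 0.174). The gap was smaller within sets, 62.2% against 69.0% in set 1 (exact p = 0.143) and 43.8% against 45.3% in set 2. In limma 0 of 27 segments passed (4 unadjusted; edgeR 1; 0 within set 1 and 0 within set 2), and 0 members of the lists, 0 also adjusted over the list alone. The smallest p were those of TRBJ1-3 (log2 0.98, SE 0.39, adjusted p = 0.202), TRBV3 (1.59) and TRBV12-1 (-1.06). Of 90 pairs 0 passed (3 unadjusted) and of 10 shared clonotypes 0 (0 unadjusted). Without PTX mouse 11, whose TRBV24 share was 32.2%, 8 segments passed, and without PLX+PTX mouse 12, 2 did.

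PLX+PTX against PLX asked what chemotherapy added to CSF1R inhibition. TRBV24 rose from 15.5% ± 4.29 (n = 5) to 46.7% ± 23.3 (n = 5), higher in 5 of 5 mice than in every PLX mouse (exact p = 0.00794; within set 2 43.8% in 2 mice, exact p = 0.0476, the smallest possible). TRBV3 fell from 11.1% to 2.52% ± 3.08, TRBV4 from 16.6% to 5.92%, TRBV20 from 1.52% to 0.0554% and TRBV13-3 from 0.854% to 0.0569%. In limma 10 segments passed, 2 higher and 8 lower (16 unadjusted, edgeR 6). With the set as a block 14 passed, 2 higher and 12 lower, and these held all 10 with the same direction; within set 2 alone 0 passed (7 unadjusted). Log2 differences were -3.42 for TRBV3 (SE 0.79; -3.55 with the block), -2.92 for TRBV20, -2.35 for TRBV13-3, -2.15 for TRBV4, -1.72 for TRBV13-1, -1.65 for TRBV12-1, 1.46 for TRBV24 (1.53 with the block), -1.10 for TRBJ1-3, -0.96 for TRBJ1-4 and 0.73 for TRBJ2-5. Of list 1, 3 of 4 fell (4 adjusted over the list alone), of list 2 1 of 4 (1), of list 3 0 of 3 (2), of the TRBJ1 cluster 2 of 5 (2), and of the TRBJ2 cluster 1 of 6 rose (1). Without TRBV24, 3 segments were higher and 5 lower. Of 90 pairs 31 passed, 13 higher and 18 lower, and 26 with the block, but counting each clonotype once left 4 segments and 1 pair, and leaving out 1 mouse gave 5 to 16 segments and 15 to 40 pairs. The named pairs were TRBV3 TRBJ2-4 (-2.69), TRBV3 TRBJ2-7 (-2.68), TRBV3 TRBJ2-3 (-2.47), TRBV2 TRBJ2-7 (-2.45) and TRBV3 TRBJ2-5 (-2.42). Of 10 shared clonotypes 0 passed (1 unadjusted). Clonotypes numbered 8301 against 2500 and entropy was 8.28 against 6.87 (each exact p = 0.00794, adjusted 0.102), so no summary value passed, and similarity differed by 0.0353 (exact p = 0.0556, adjusted 0.204).

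The 4 groups formed a 2 by 2 design, which allowed a test of whether the PLX difference depended on PTX. The interaction passed for 17 of 27 segments in limma, 2 positive and 15 negative (edgeR 14). With the set as a block, 15 of these 17 passed in the same direction (12 when the R mice were also left out). All untreated mice were in set 1 and all PLX mice in set 2. The part of the interaction that came with the set is therefore open. Counting each clonotype once left 4 segments and 0 pairs, and leaving out 1 mouse gave 13 to 19 segments and 12 to 38 pairs. Interactions were -4.34 for TRBV3 (SE 1.05, adjusted p = 0.00251), -3.83 for TRBV4, -3.10 for TRBV13-3, -2.93 for TRBV20, -2.83 for TRBV2, -2.66 for TRBV29, -2.61 for TRBV13-2, -2.43 for TRBV13-1 and -2.38 for TRBV26 and TRBV19. TRBV20 averaged 0.000685% in untreated, 0.000827% in PTX and 0.0554% in PLX+PTX mice. These lie below the added 0.1, so its interaction rests on the PLX mice. TRBV24 had an interaction of 1.87 (SE 0.44, adjusted p = 0.00251, and 1.78 with the block). All 4 tested members of list 1 and all 4 of list 2 had negative interactions that passed (4 and 4 adjusted over the list alone), as did 2 of 3 in list 3 (2) and 2 of 5 in the TRBJ1 cluster (2), while the TRBJ2 cluster had 1 positive and 1 negative (1). Of 16 segments other than TRBV24, 10 also passed without it. Of 90 pairs 30 passed, 7 positive and 23 negative, 20 with the block and 9 when the R mice were also left out; TRBV4 TRBJ2-7 (-3.62), TRBV3 TRBJ2-7 (-3.39), TRBV2 TRBJ2-7 (-3.03), TRBV3 TRBJ2-4 (-3.01) and TRBV4 TRBJ2-4 (-2.90) were the largest. None of the 7 summary values passed, and the number of clonotypes had an interaction of 4312 (permutation p = 0.0169, adjusted 0.118). This permutation assumes no PLX difference with or without PTX. Its p therefore does not test the interaction apart from a PLX difference.

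aPD-L1 alone was compared with untreated mice, all in set 1. TRBV24 was 73.3% ± 9.97 (n = 3) against 80.7% ± 8.73 (n = 6; exact p = 0.274), and clonotypes numbered 6169 ± 1265 against 3168 ± 1033 (exact p = 0.0119, the smallest possible, adjusted 0.115). No segment passed in limma (0 of 27, 0 unadjusted; edgeR 0), no list member passed, 0 also adjusted over the list alone, and 0 pairs and 0 shared clonotypes passed (0 unadjusted for both). The smallest p were those of TRBV1 (log2 0.68, SE 0.42, adjusted p = 0.989), TRBJ1-1 (0.48) and TRBV5 (0.69).

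PTX+aPD-L1 against PTX asked what the aPD-L1 treatment added to chemotherapy. List 1 segments summed to 6.34% ± 4.17 (n = 4) and 1.80% ± 1.42 (n = 7), which did not pass after adjustment (exact p = 0.0212, adjusted 0.117; in set 1 against 2.47%, p = 0.0952). The list 1 sum was 0.319% in PTX+aPD-L1 mouse 1 and 6.94% to 9.69% in the other PTX+aPD-L1 mice. TRBV13-1 had 1.15% ± 0.766 against 0.280% ± 0.212 (log2 1.57, SE 0.54, adjusted p = 0.162), TRBV12-1 a log2 of 1.20 and TRBV13-2 1.64. In limma 0 of 27 segments passed (2 unadjusted, edgeR 0), with 1 member of list 1 adjusted over the list alone and 0 of the other lists. Of 90 pairs 0 passed (2 unadjusted), and of 10 shared clonotypes 0 (0 unadjusted).

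**Figure D4:**
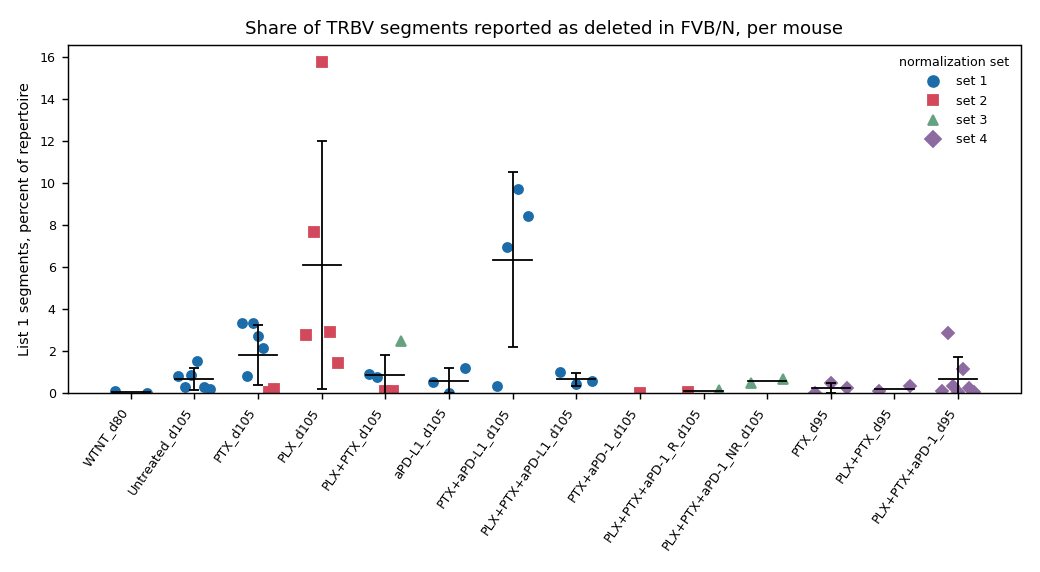
Summed share of the 9 segments of list 1, reported as deleted in FVB/N (percent of the repertoire, vertical axis), with 1 point per mouse colored by normalization set, a line at the mean of groups of 2 or more and SD bars for groups of 3 or more. Means are 6.34% in PTX+aPD-L1, 6.10% in PLX and 0.656% in untreated mice. PLX mouse 3, with 1383 reads, has 15.8%, and PTX+aPD-L1 mouse 1 has 0.319%. In the repertoire without TRBV24, PLX and untreated means are 7.07% and 4.57%.

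The triple treatment PLX+PTX+aPD-L1 was compared with each pair. Against PLX+PTX, TRBJ1-3 fell from 0.971% ± 0.660 (n = 5) to 0.188% ± 0.102 (n = 3; log2 -1.72, SE 0.49, adjusted p = 0.0297, lower in 3 of 3 mice than the PLX+PTX mean), and -1.27 with the set as a block (adjusted p = 0.305). It was the single segment of 27 past the threshold in limma (10 unadjusted, edgeR 11; 0 with the block, 1 within set 1). With 1 mouse left out 0 to 10 segments passed, and 0 without any 1 of 5 of the 8 mice. In list 2, 0 of 4 members passed (3 adjusted over the list alone), and in the TRBJ1 cluster 1 of 5 fell (2). Clonotypes above 0.1% took 31.9% against 9.23% (exact p = 0.0357, adjusted 0.189). Against the 2 PLX+PTX mice of set 1, with 17.4%, the exact p was 0.3, with 0.1 the smallest possible. Of 90 pairs 0 passed (20 unadjusted), and of 10 shared clonotypes 0 (1 unadjusted). Against PTX+aPD-L1, both in set 1, TRBV13-1 fell from 1.15% ± 0.766 (n = 4) to 0.108% ± 0.0442 (n = 3) and TRBV12-1 from 0.834% ± 0.546 to 0.0748% ± 0.0435, both in 3 of 3 mice against the PTX+aPD-L1 mean. Their log2 differences were -2.22 (SE 0.66) and -2.09 (SE 0.66; adjusted p = 0.0404 for both, 0.0181 with the block). These 2 members of list 1 were the segments that passed of 27 (4 unadjusted, edgeR 0), with 4 of list 1 adjusted over the list alone and 0 without TRBV24. Leaving out any 1 of 6 of the 7 mice gave 0, and leaving out PTX+aPD-L1 mouse 1 gave 4. Limma on the mice of set 1 alone passed TRBV13-1 (log2 -2.22) and TRBV13-3 (-1.78), each with adjusted p = 0.0268. There TRBV12-1 did not pass (log2 -2.09, adjusted p = 0.0603). Summed list 1 shares were 0.319%, 6.94%, 9.69% and 8.42% in PTX+aPD-L1 mice 1, 4, 6 and 7. In triple-treated mice 2, 3 and 5 they were 0.984%, 0.420% and 0.549%, so PTX+aPD-L1 mouse 1 lay below each of these. Of 90 pairs 0 passed (2 unadjusted), and of 10 shared clonotypes 0 (1 unadjusted).

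At day 95, PLX+PTX+aPD-1 was compared with PTX, all in set 4. TRBV24 took 28.5% ± 8.97 (n = 7) and 29.2% ± 2.86 (n = 3) of the repertoire (exact p = 0.933), and TRBV1 27.0% ± 7.17 and 19.6% ± 0.152. In limma 0 of 27 segments passed (0 unadjusted, edgeR 0), no list member passed and 0 also adjusted over the list alone. The smallest p were those of TRBJ1-2 (log2 -0.46, SE 0.26, adjusted p = 0.980), TRBJ2-7 (-0.24) and TRBJ2-4 (0.22). Of 90 pairs 0 passed (7 unadjusted) and of 10 shared clonotypes 0 (0 unadjusted).

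PTX mice of d105 were compared with those of day 95. TRBV24 was higher at d105, 62.3% ± 13.9 (n = 7) against 29.2% ± 2.86 (n = 3), in 7 of 7 mice against the day 95 mean (log2 1.05, adjusted p = 0.0119; exact p = 0.0167). TRBV3 was lower with 0.537% against 4.75% (log2 -3.78, SE 0.86), TRBV19 with 1.14% against 8.10% (-3.43), TRBV4 by -2.78, TRBV29 by -2.64, TRBJ1-3 by -2.35, TRBV2 by -2.30, TRBV26 by -2.27, TRBJ1-1 by -1.39 and TRBJ1-4 and TRBJ2-2 by -1.11 each. In limma 12 segments passed, 2 higher and 10 lower (15 unadjusted, edgeR 13), and without TRBV24 6 were higher and 12 lower, with all 11 others in the same direction. List 2 had 3 of 4 lower (3 adjusted over the list alone), list 3 1 of 3 (1), the TRBJ1 cluster 3 of 5 (3), list 1 0 of 4 (0), and the TRBJ2 cluster 1 higher and 1 lower of 6 (2). List 2 summed to 4.05% against 21.1% and the TRBJ1 cluster to 12.3% against 22.7% (each exact p = 0.00833, the smallest possible, adjusted 0.0680). Counting each clonotype once left 3 segments and 17 pairs, and leaving out 1 mouse gave 10 to 15 segments and 27 to 63 pairs. Of 90 pairs 56 passed, 5 higher and 51 lower, led by TRBV3 TRBJ2-7 (-3.35), TRBV19 TRBJ2-7 (-3.17), TRBV4 TRBJ2-7 (-2.71), TRBV19 TRBJ2-2 (-2.57) and TRBV29 TRBJ2-7 (-2.44), and of 10 shared clonotypes 0 passed (3 unadjusted). Repertoires were more alike within than between days by 0.0232 (exact p = 0.00833, adjusted 0.0458), and by 0.0188 without mice under 1000 clonotypes (exact p = 0.0278, the smallest possible with 7 and 2 mice, adjusted 0.153). Clonotypes shared by 2 mice had identical nucleotide sequences in 79.7% of cases among PTX mice of day 95 and in 27.0% among those of d105. All day 95 mice were in set 4 and no d105 mouse was, so day and set cannot be told apart. In the comparisons for which no similarity has been given, within-minus-between differences ranged from -0.00408 to 0.00752, with adjusted p from 0.629 to 0.834.

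The 2 FVBN WTNT mice of day 80, without the transgene, differed from untreated mice in age as well. TRBV30 was lower with 0.290% ± 0.326 against 0.897% ± 0.116 (log2 -1.66, SE 0.46, adjusted p = 0.0247), TRBV1 with 6.36% ± 6.90 against 13.7% ± 6.65 (-1.48) and TRBJ2-1 (log2 -0.53; both adjusted p = 0.0351), each in 2 of 2 mice against the untreated mean. These were the 3 of 27 past the threshold in limma (6 unadjusted, edgeR 0), and without TRBV24 1 passed. Both groups were in set 1, and limma on the mice of that set alone passed 8 segments, 2 higher and 6 lower, TRBV30 and TRBJ2-1 among them but not TRBV1 (adjusted p = 0.0663). With a mouse left out, log2 differences ranged from -2.64 to -0.68 for TRBV30, -2.90 to -0.06 for TRBV1 and -0.76 to -0.31 for TRBJ2-1, and without WTNT mouse 1, which left 1 WTNT mouse, no segment passed. Of list 3, 1 of 3 fell (1 adjusted over the list alone), and of the TRBJ2 cluster 1 of 6 (2). TRBV24 was 90.7% against 80.7% (exact p = 0.357, with 0.0357 the smallest possible). Of 90 pairs 0 passed in limma, with 7 unadjusted for WTNT and 6 for R against NR, and of 10 shared clonotypes 0, with 1 and 0 unadjusted. Among PLX+PTX+aPD-1 mice of d105, 2 R and 2 NR mice gave 0 of 27 segments in limma (3 unadjusted, edgeR 0), and 0 list members, 0 also adjusted over the list alone. With any 1 mouse left out, 1 mouse stood alone in its group, and the count changed with the mouse removed. In set 3 alone, the 1 R mouse had a TRBV20 log2 of 3.08 against 2 NR mice. In such fits the lone mouse gives no spread of its own. TRBV1 had 8.15% against 19.8% (log2 -1.40, SE 0.59, adjusted p = 0.422), TRBV19 a log2 of -2.38 and TRBV29 -2.09. TRBV24 took 91.9% in R mouse 2 (90.8% of reads, 95% Wilson interval 90.4% to 91.2%) and 15.5% in R mouse 4 (19.7% of reads, 19.6% to 19.8%). It took 39.2% in NR mouse 5 (38.2% of reads, 37.9% to 38.4%) and 23.5% in NR mouse 7 (26.8% of reads, 26.7% to 26.9%).

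The most abundant clonotypes shared by at least 26 mice were TRBV24 TRBJ2-7 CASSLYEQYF (mean 720 ppm, 27 mice), TRBV1 TRBJ2-5 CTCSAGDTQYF (534, 32 mice), TRBV24 TRBJ2-7 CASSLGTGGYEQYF (377, 26 mice), TRBV1 TRBJ2-7 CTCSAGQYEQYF (252, 28 mice) and TRBV1 TRBJ2-7 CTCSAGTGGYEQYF (193, 30 mice). Without the mouse in which each was highest, these means were 464, 495, 341, 163 and 112, so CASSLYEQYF and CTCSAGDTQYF changed places. By the same measure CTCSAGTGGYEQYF fell below TRBV1 TRBJ2-4 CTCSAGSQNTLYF (155), TRBV5 TRBJ2-7 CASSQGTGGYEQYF (118) and TRBV1 TRBJ2-1 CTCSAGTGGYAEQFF (117). The largest single clonotype, TRBV4 TRBJ2-7 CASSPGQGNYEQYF, took 9.98% in PLX mouse 3, from 50 of 1383 reads (3.62%, 95% Wilson interval 2.75% to 4.73%). TRBV24 TRBJ2-5 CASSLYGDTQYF took 8.24% in PTX mouse 6 of d105 (4.91% of reads, 4.71% to 5.11%), and TRBV24 TRBJ2-7 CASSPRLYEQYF 5.76% in R mouse 2 (5.36% of reads, 5.05% to 5.69%). TRBV24 TRBJ2-5 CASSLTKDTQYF took 5.23% in aPD-L1 mouse 1 (3.29% of reads, 3.23% to 3.36%), and TRBV4 TRBJ1-3 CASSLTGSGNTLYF 3.85% in PLX+PTX+aPD-1 mouse 2 of day 95 (1.12% of reads, 0.892% to 1.41%). The shares of the score and of reads differ because the normalized value weights each V-J pair.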

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

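Apart from the comparison of PLX mice with other mice of set 2, whose prediction was written first, the tests weighed here were chosen after the results they concern were seen.

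A first pattern was the low TRBV24 share in PLX mice against untreated mice, which came with the normalization set. With the set as a block the log2 difference was -1.84 (SE 0.35, adjusted p = 0.000107) against -2.42 (SE 0.31) without it, and -1.74 (SE 0.33) when the 2 R mice, with 91.9% in set 2 and 15.5% in set 3, were also left out; this argues against the set as the whole cause, although few PTX and PLX+PTX mice then link the sets. Counting each clonotype once left -1.33 (SE 0.27), which argues against more reads per TRBV24 clonotype as the whole cause; the median ratio of TRBV24's share of the repertoire to its share of clonotypes was 3.61, 1.44, 1.45 and 1.72 in sets 1 to 4, so this may still account for part of it. Leaving out mice under 1000 clonotypes gave -2.23 (SE 0.34), which argues against low yield. PTX mice of d95, given no PLX and all in set 4, also had less TRBV24 than untreated mice (29.2% against 80.7%). They had more TRBV3 (4.75% against 0.0924%) and TRBV4 (10.1% against 0.438%). No d105 mouse was in set 4, so the block cannot test a cause shared with these mice. An effect of PLX itself stays open, and so does a technical difference, confined to the PLX libraries or not.

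A second pattern was the presence of list 1 segments in 3479 of 226139 clonotypes, although FVB/N is reported to lack those genes. Of 1124 TRBV13-2 clonotypes, 90.0% began with CASG against 0.313% outside list 1. The clonotype caller is not given, and the start of the CDR3 may itself have entered the V call. These values therefore cannot decide whether reads of other segments were assigned to TRBV13-2. The other list 1 segments were not tested in this way. Pairs of mice that shared a list 1 clonotype had an identical nucleotide sequence in 72.6% of 1070 cases. For TRBV20, TRBV23 and TRBV30 it was 28.6% of 168, so carry-over between libraries may be a source. A sequence found in many mice enters many pairs, so a few sequences weigh heavily in the list 1 value. The most widespread were found in 20, 13 and 12 mice. In PTX+aPD-L1 mice at most 8.71% of the list 1 share lay in clonotypes found in 3 or more mice. This argues against 1 common source of few clonotypes there. A source of many clonotypes, of which each library took a different part, would also give a low value and stays open. In PLX mice 1, 2, 3, 4 and 6 that part was 65.8%, 27.9%, 0%, 73.3% and 54.5%. It was 92.3% in PLX+PTX mouse 15 and 0% to 33.7% in the other PLX+PTX mice of d105. A common source therefore stays open in most PLX mice. A mixed strain background cannot be told apart, since no label gives it; the highest share in a WTNT mouse was 0.0889%.

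Another pattern was the similarity of PLX repertoires to each other. Without the 10 largest clonotypes of each mouse the within-minus-between difference was 0.0253 (exact p = 0.00216), which argues against a few large clonotypes as the whole cause. Within set 2, PLX pairs were more alike than PLX mice and the other 6 mice, 0.102 against 0.0124, a difference of 0.0893 (one-sided exact permutation p = 0.0108), which argues against the set as the whole cause, but PLX mice 2, 4 and 1 were also like PLX+PTX mouse 15 of set 3 (0.215, 0.167 and 0.152). Shared clonotypes had identical nucleotide sequences in 68.9% of cases among PLX mice and 22.0% among untreated mice, but also in 79.7% among PTX and 65.1% among PLX+PTX mice of d95 (13.1% to 28.9% in the other groups), so carry-over between libraries may contribute and would not be confined to PLX. An effect of PLX on shared clonotypes stays open and was not tested apart from this.

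Of 72 sets of values tested for a mouse far from the rest of its group (12 measures in 6 groups), 15 held one. Chance gives about 5%, but the 12 measures are not independent. For the share above 1%, a mouse above 0% is flagged whatever its value where all others had 0%. This held for PLX mouse 3, PLX+PTX mouse 15 of d105 and PTX+aPD-L1 mouse 7, so 5% does not apply to them. PLX mouse 3, with 128 clonotypes, stood apart in clonality (0.130), Shannon entropy (4.20), the share in the 10 largest clonotypes (36.6%), above 1% (62.4%), above 0.1% (98.5%) and mean CDR3 length (13.1). PLX+PTX+aPD-1 mouse 2 of d95, with 209 clonotypes, had 36.1% in clonotypes above 1% and a list 1 share of 2.87% (2.59% of reads, 95% Wilson interval 2.23% to 3.02%). PTX mouse 6 of d105 had 16.3% in its 10 largest clonotypes and 11.9793% in clonotypes above 1%. PTX mouse 11 of d105 had a TRBV24 share of 32.2% (36.0% of reads, 35.6% to 36.3%) and a list 2 share of 14.6% (13.2% of reads, 12.9% to 13.4%). PLX+PTX mouse 9 of d105 had 1.19% in its 10 largest clonotypes, the lowest of its group. In clonotypes above 1%, PLX+PTX mouse 15 of d105 had 1.94% and PTX+aPD-L1 mouse 7 had 2.38%, with 0% in each of the others of its group.

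The interaction of PLX and PTX passed in 17 segments and 30 V-J pairs. With the set as a block 16 segments and 20 pairs passed, 12 and 9 when the R mice were also left out, and 4 and 0 when each clonotype was counted once; without TRBV24, 10 of the 16 other segments did. Untreated and PLX mice shared no set, so the part of this that came with the set is open. Log2 interactions were -4.34 for TRBV3, -3.83 for TRBV4, -3.10 for TRBV13-3, -2.93 for TRBV20, -2.83 for TRBV2 and -2.66 for TRBV29. They were -2.61 for TRBV13-2, -2.43 for TRBV13-1 and -2.38 for TRBV26 and TRBV19. The TRBV20 value rests on the PLX mice, since its mean in untreated, PTX and PLX+PTX mice lay below the added 0.1.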

How the results depend on the processing

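Alternatives chosen after the data were seen were the first normalized count, the set as a block with and without the R mice, tests within sets, set 1 alone, removal of TRBV24, removal of mice under 1000 clonotypes and edgeR; the others were fixed in advance. Where a result changed, the cause was not tested unless stated. No paired analysis was possible because replicate numbers follow the order of samples and link no mice between groups. Of the values of the up to 10 largest segment differences of each comparison that passed, 683 kept direction and side of the threshold under other settings, 2 changed sign (TRBV5, PLX against untreated, -0.27 without TRBV24 with the set as a block and -0.30 when the R mice were also left out) and 221 no longer passed. With a mouse left out, 622 kept both and 74 no longer passed. Among smaller differences that passed, without TRBV24 TRBV23 turned from 1.08 to -0.82 (PLX against untreated; -0.68 with the block, -0.66 also without R mice) and TRBV1 from 0.85 to -0.68 (PLX+PTX against untreated; -0.10 and -0.16). Counting clonotypes once turned that TRBV1 to -0.14. The TRBV5 interaction turned from -1.95 to 0.38 without TRBV24 with the block and 0.44 also without R mice. For PLX+PTX against untreated, 4 summary values passed (entropy, percent above 0.1%, clonotypes, CDR3 length), and 0 did under the following, with differences in that order: thinning 0.358, -28.0, 272 and 0.234; animal numbers below 34000, and also within sets, 0.744, -28.1, 3471 and 0.134 (2 against 6 mice, too few for a value to pass after adjustment, with the smallest possible exact p of 0.0357 for the first 3); medians 1.08, -39.8, 4720.5 and 0.116; the first normalized count 1.10, -35.7, 5133 and 0.204; without TRBV24 within sets, with the same 8 mice and the same limit, 0.996, -35.6, 3105.5 and 0.179. The first normalized count left entropy, clonotypes and CDR3 length at the smallest possible exact p of 0.00216, and their adjusted p rose because percent above 0.1% no longer reached it. Raw counts ended the call for percent above 0.1% (-34.5, adjusted p = 0.0667), removal of TRBV24 clonotypes ended it for CDR3 length (0.240), and both gave 1 value that passed for PTX against untreated. With fewer mice the smallest possible p rises, so leaving out any mouse also gave 0 to 0 although each of the 4 stayed at that p, with ranges of 0.921 to 1.24, -39.5 to -32.6, 3845 to 5796 and 0.162 to 0.212. Segment counts changed as follows. The set as a block gave 0 for PLX+PTX against untreated and 0 for PLX+PTX+aPD-L1 against PLX+PTX; set 1 alone gave 0 for PLX+PTX against untreated and 8 for WTNT against untreated; the animal number range as a block gave 0 for PLX+PTX against untreated, 16 for PLX+PTX against PLX and 0 for PLX+PTX+aPD-L1 against PLX+PTX. For PLX+PTX against untreated, counting clonotypes once gave 0, fitting the compared groups alone 6 (6 higher, 0 lower) and removing TRBV24 with the block 0. For PLX+PTX against PLX, counts were 16 with arcsine and with no filter, 4 with clonotypes once, 6 with edgeR (3 higher, 3 lower), 19 with raw counts and 6 (2 higher, 4 lower) without mice under 1000 clonotypes. edgeR gave 5 for PTX against untreated and 1 for PLX+PTX against PTX. For PLX+PTX+aPD-L1 against PLX+PTX, the 1 segment became 0 with arcsine, clonotypes once, the first normalized count, compared groups alone, a pseudocount of 1, raw counts, no 10 largest clonotypes or no TRBV24 with the block, and 11 with edgeR or without TRBV24. Against PTX+aPD-L1, the 2 became 0 with arcsine, edgeR, compared groups alone, a pseudocount of 0.01, raw counts, no 10 largest clonotypes and no TRBV24 with or without the block. For PTX at d105 against d95, clonotypes once gave 3; for the interaction they gave 4, and removal of TRBV24 with the block gave 10. For WTNT, counts were 0 with arcsine, clonotypes once, edgeR, the first normalized count, compared groups alone, a pseudocount of 1 and raw counts, 1 without TRBV24 or the 10 largest clonotypes, and 5 without mice under 1000 clonotypes. The split of higher and lower moved for PLX against untreated from 18 and 4 to 12 and 5 (clonotypes once) and 13 and 6 (without TRBV24), for PLX+PTX against PLX from 2 and 8 to 3 and 5 (without TRBV24), and for PTX at d105 against d95 from 2 and 10 to 6 and 12 (without TRBV24). With the set as a block and the R mice left out, segment counts were 16 for PLX against untreated, 0 for PLX+PTX against untreated and for PLX+PTX+aPD-L1 against PLX+PTX, 13 for PLX+PTX against PLX and 12 for the interaction. Removing TRBV24 as well gave 12 for PLX against untreated, 0 for PLX+PTX against untreated and for PLX+PTX+aPD-L1 against each pair, 11 for PLX+PTX against PLX and 9 for the interaction. Pair counts with the block and without R mice were 25 for PLX against untreated, 0 for PLX+PTX against untreated, 20 for PLX+PTX against PLX, 9 for the interaction and 1 for PLX+PTX+aPD-1 at d95. Pair counts for PLX against untreated were 49 with clonotypes once (29 higher, 20 lower), 131 with no filter and 29 with the block; for PLX+PTX against untreated 0 with clonotypes once, no filter, the block or no TRBV24; for PLX+PTX against PLX 1 with clonotypes once, 72 with no filter (13 higher, 59 lower) and 14 without TRBV24 (4 higher, 10 lower); for PTX at d105 against d95 17 with clonotypes once and 37 without TRBV24. No filter also gave 21 pairs for PTX+aPD-L1 against PTX, 25 for PLX+PTX+aPD-L1 against PTX+aPD-L1 and 3 for PLX+PTX+aPD-1 at d95, which had 1 with the first normalized count and with the block. Interaction pairs were 0 with clonotypes once and 54 without mice under 1000 clonotypes (7 positive, 47 negative), and 7 positive with 14 negative with the first normalized count. Without mice under 1000 clonotypes, PLX+PTX against PLX had 8 pairs higher and 32 lower, and with a pseudocount of 0.01 PLX+PTX against untreated had 50 higher and 1 lower. Shared clonotypes, 0 in each comparison, were 1 for PLX+PTX against PLX by CDR3 alone or with clonotype number as a covariate, 1 for PLX+PTX+aPD-L1 against PTX+aPD-L1 with the first normalized count, and 1 for it and for PTX against untreated with 1 ppm. Clonotypes in 13 or more mice gave 1 for PTX, 4 for PLX and 1 for aPD-L1 against untreated, 3 for PLX+PTX against PLX, 1 for PLX+PTX+aPD-1 at d95 and 2 for PTX at d105 against d95. Similarity differences turned with Jaccard to 0.000295 (PLX+PTX against PTX), 0.000191 (PTX+aPD-L1 against PTX) and 0.00058 (PLX+PTX+aPD-L1 against PLX+PTX), and that of PLX+PTX against PLX passed with 0.00648. Animal numbers below 34000 turned them to -0.00169 (PTX) and -0.00627 (PLX+PTX) against untreated and 0.00102 (PTX+aPD-L1 against PTX). Without the 10 largest clonotypes, PLX+PTX against PLX passed with 0.0183 and PLX+PTX+aPD-L1 against PLX+PTX turned to 0.00119. Without mice under 1000 clonotypes, PLX against untreated had 0.0626 and PTX at d105 against d95 0.0188, each at the smallest exact p that the fewer mice allow (0.00476 and 0.0278), so that neither passing came from the number of mice. With a mouse left out, segment counts ranged from 5 to 15 for PLX+PTX against untreated (5 without PLX+PTX mouse 9 or 15), 0 to 8 against PTX (2 without PLX+PTX mouse 12, 8 without PTX mouse 11), 5 to 16 against PLX (16 without PLX+PTX mouse 9, 5 without 12) and 0 to 3 for PTX+aPD-L1 against PTX (3 without PTX+aPD-L1 mouse 1). For PLX+PTX+aPD-L1 they ranged from 0 to 10 against PLX+PTX (10 without PLX+PTX mouse 3, 9 without 12, 0 without 6, 9 or 15 or triple-treated mouse 2 or 3) and 0 to 4 against PTX+aPD-L1 (4 without PTX+aPD-L1 mouse 1, 0 without any other mouse). They were 0 to 4 for WTNT (0 without WTNT mouse 1, 1 without untreated mouse 3, 4 or 12) and 0 to 15 for R against NR (15 without R mouse 4, where 1 R mouse of set 2 stood against 2 NR mice of set 3 and the other groups supplied the spread). Pair counts ranged from 0 to 65 for PLX+PTX against untreated (1, 28, 20, 29, 3 and 21 without untreated mouse 2, 3, 4, 6, 11 and 12, and 0 and 1 without PLX+PTX mouse 9 and 15), 15 to 40 against PLX (15 without PLX+PTX mouse 3 or 12), 27 to 63 for PTX at d105 against d95 (32 and 27 without d95 mouse 2 and 3) and 12 to 38 for the interaction (12 without PLX+PTX mouse 3 or 12, 18 without 6 or PTX mouse 11). They were 0 to 1 for PTX+aPD-L1 against PTX and PLX+PTX+aPD-L1 against PTX+aPD-L1 (1 without PTX+aPD-L1 mouse 1) and for PLX+PTX+aPD-1 at d95 (1 without its mouse 1 or 5). Shared clonotypes ranged from 0 to 1 for PTX against untreated (1 without untreated mouse 3), PLX against untreated (untreated mouse 4 or PLX mouse 6), PLX+PTX against PLX (PLX mouse 4) and PTX at d105 against d95 (d105 mouse 6 or 7). Similarity ranged from 0.0356 to 0.0626 for PLX, -0.000921 to 0.00261 for PTX (negative without untreated mouse 6, 11 or 12 or PTX mouse 8 or 11), -0.000188 to 0.00532 for PLX+PTX (negative without PLX+PTX mouse 9) and -0.00878 to 0.00447 for aPD-L1 (positive without aPD-L1 mouse 2 or 5), each against untreated. It ranged from -0.00491 to 0.000107 for PLX+PTX against PTX (positive without PTX mouse 11), 0.0170 to 0.0673 against PLX (passing without PLX+PTX mouse 15), -0.00776 to -0.000331 for PTX+aPD-L1 against PTX, -0.00927 to 0.000958 for PLX+PTX+aPD-L1 against PLX+PTX (positive without PLX+PTX mouse 3) and -0.00309 to 0.0127 against PTX+aPD-L1 (negative without PTX+aPD-L1 mouse 6). It was -0.00522 to 0.00593 for PLX+PTX+aPD-1 at d95 (positive without its mouse 2, 3, 4, 6 or 7) and 0.0188 to 0.0295 for PTX at d105 against d95. This no longer passed without any 1 of the 10 mice, each time at the smallest exact p possible (0.0119 or 0.0278), so the number of mice decided it. Depth limits small shares: in the mouse with 1383 reads, 3 reads are 0.217% of the total. Productive clonotypes alone gave identical values, and clonotypes in 39 or more mice numbered 0, so that definition gave no value.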

Other observations

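The counts of other splits of the mice were made after the results were seen; the other values in this part come without a test.

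A few groups entered no planned comparison. The PTX+aPD-1 mouse of d105 had a TRBV24 share of 66.6% (63.5% of reads, 95% Wilson interval 63.1% to 63.8%), 11073 clonotypes and an entropy of 8.69 nats. The PLX+PTX mice of d95 had TRBV24 shares of 21.9% (24.7% of reads, 24.5% to 24.9%) and 38.1% (39.4% of reads, 38.9% to 39.8%), with 3189 and 1269 clonotypes. R mice 2 and 4 had 3904 and 10092 clonotypes and entropies of 7.39 and 8.66, and NR mice 5 and 7 had 5328 and 13826 clonotypes and entropies of 7.85 and 8.90. The TRBV13-2 TRBJ2-5 clonotype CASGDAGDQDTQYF was listed with 2 nucleotide sequences, of which 1 was found in 20 mice of 12 groups and all 4 sets. Morisita-Horn similarity had a median of 0.0169 over 1326 pairs of mice, 0.0345 within a set and 0.0131 between sets.

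Other splits of the same mice were counted for each model; the counts include the real split, the splits took no account of the set, and where more than 100 were possible 100 were drawn. For PLX against untreated, with 100 drawn of 462, 1 of 100, the real split itself, gave 22 segments (highest other drawn 20) and 1 of 100, again the real split, 74 pairs (69). Splits that were not drawn may reach these counts. The share of those drawn makes chance unlikely but does not exclude it, and this split is also that of set 2 against set 1. For PLX+PTX against untreated, again with 100 drawn of 462, 1 of 100 gave 15 segments (13) and 1 of 100 gave 47 pairs (36), the real split in both cases. On that share chance is unlikely but not excluded, since without 1 mouse pairs fell to 0. The set stays open too, since 0 segments and 0 pairs passed with the set as a block. For the interaction, 2 of 100 reached 17 segments (17) and 4 of 100 reached 30 pairs (67). A split with 67 pairs points to a structure of the samples, so these counts do not tell the groups from the set. For PTX at d105 against d95, with 100 drawn of 120, 5 of 100 reached 12 segments (16), where chance cannot be excluded, and 2 of 100 reached 56 pairs (62); another split gave more pairs than the real one, and day and set coincide, so this count does not settle it. For PLX+PTX against PLX, with 100 drawn of 126, 5 of 100 reached 10 segments (15) and 5 of 100 reached 31 pairs (51), so chance cannot be excluded. For PLX+PTX+aPD-L1, 6 of 56 splits reached the 1 segment found against PLX+PTX (15), and 4 of 35 the 2 found against PTX+aPD-L1 (4), so chance cannot be excluded.

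Where the real count was 0, every split counts as being as large. This was so for segments and pairs in 100 of 100 splits of PTX against untreated (highest other 2 segments and 0 pairs), of PLX+PTX against PTX (14 and 58), of PTX+aPD-L1 against PTX (2 and 2) and of PLX+PTX+aPD-1 against PTX at d95 (2 and 14). It was also so in 84 of 84 splits of aPD-L1 against untreated (1 and 0), and for pairs in 56 of 56 splits of PLX+PTX+aPD-L1 against PLX+PTX (64) and 35 of 35 against PTX+aPD-L1 (2). The splits with 14 segments, 58 pairs and 64 pairs point to a structure of the samples that the groups do not follow. For shared clonotypes the real count was 0 in all 12 tests, in 100 of 100, 84 of 84, 56 of 56 or 35 of 35 splits, with 1 or 2 as the highest other.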
